A study of Mus musculus with 8 samples.

How the data were processed

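Total RNA from 8 mouse melanomas was labelled with biotin and hybridised to Illumina bead arrays, 1 array per tumour, per the labels' protocols. The deposited data hold a table of probe intensity on a linear scale with a detection p-value for each probe and array, and a table of normalized probe intensity. GenomeStudio is the tool named in the submitters' processing notes, with its version not given in the sources used here. The deposited intensity of the first table lies between 46.7 and 38501.9 with array medians from 86.3 to 94.8, so it was taken as not background-subtracted and not normalized. The authors' normalized intensity has array medians from 90.4 to 90.7 and ranks the probes of each array as the first table does (Spearman coefficient at least 0.999998). It is therefore linear and scaled to a common distribution by a monotone step, and the name of that step is not given in the sources used here. The normalized table was used only as an alternative.

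Groups were taken from the sample titles: 7 resistant tumours with NRAS off and 1 control with NRAS on. Of 25697 probes, 23978 have 1 gene symbol in the platform annotation, 0 have several and 1719 have none. Symbols were brought up to date by gene ID through the RefSeq gene table of assembly GRCm38.p6, which matched 23962 probes, and no coordinates were taken from it. Intensities were corrected for background with limma's neqc, which fits a normal plus exponential model whose background is inferred from the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 1 of the 8 arrays were kept (15067, of which 14190 are named). Each of the 10461 genes was represented by its probe with the highest mean. Of 108 genes named by rule, 30 had more than 1 detected probe, and in 8 of these a probe differed in sign from the one used: Gatad1, Shc1, Snai1, Tnc, Tyms, Col3a1, Smtn and Mdk. A gene with no probe detected in any tumour of a group has only a bound there. Its fold was computed against the mean of, per array, the higher of the lowest signal among detected probes and the gene's own signal, and is given as "at least".

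Resistant tumours were compared with the control by limma's lmFit and eBayes with Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. With 1 control, all 6 residual degrees of freedom come from the resistant tumours. All adjusted p-values of genes are limma's. Each of the 8 tumours was also set against the other 7 in the same way. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, whose p asks whether the genes of a list move on balance one way. There were 24 lists, for signalling, pigment cell state, stress and growth programs and the other cell types a tumour can hold. Lists, tests, the rule for named genes and all alternatives except those said to be added later were fixed before the data were examined. The rule names the targeted genes, up to 10 genes per direction with the largest changes among those that passed and had all 7 tumours on one side, filled to 10 with the smallest p-values, the 3 members of each list with the smallest p, the 10 genes most variable among resistant tumours, and receptor, ligand and MAPK output genes with 1 tumour apart. Predicted genes and clone names were skipped among the changed and the most variable genes. Spread within a list was ranked among 10000 random lists matched on mean expression in 20 bins. Alternatives covered background correction, normalization, the deposited normalized values, the detection filter, the variance model, the probe rule, a 2-fold limit and leaving out each resistant tumour. The table columns name no chip or array position, so no batch could be tested.

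The test was checked on 20 simulated sets of 10461 genes with the real means and spreads, 7 tumours against 1. It recovered 7.61% of 2-fold, 52.1% of 4-fold and 83.8% of 16-fold changes, and 6.11% of its calls were false. These shares need not hold where a single tumour differs from the others in many genes at once, as resistant tumour 6 does below. The number of arrays limits the precision. R 4.3.3 and limma 3.58.1 were used.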

Results

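Gene expression was measured on Illumina bead arrays in 8 mouse melanomas, 7 of them resistant to the loss of their driving oncogene and 1 a control in which the oncogene stayed on. The tumours came from FVB/n mice whose melanocytes carry the avian virus receptor TVA under the Dct promoter and floxed copies of Ink4a/Arf, the tumour suppressor locus also called Cdkn2a. Avian leukosis viruses brought in the Q61R form of NRAS, a small GTPase at the head of the MAPK pathway, under a Tet-off switch, together with Cre recombinase, which deletes the floxed locus. Doxycycline food, given once tumours reached 1000 mm3, shut NRAS off, and the 7 resistant tumours are ones that no longer responded to this. The comparison asks how tumours that grow without oncogenic NRAS differ from one that still had it. Each tumour was read on 1 array, with between 11821 and 12851 of 25697 probes detected and 12225 in the control, and the number of arrays limits the precision. The labels do not say that the 7 tumours came from 7 mice, so the p-values measure only the spread between these samples. The control's description names an NRAS and Cre construct without the Tet-off elements that the descriptions of the resistant tumours name, so the virus used for it is not settled by the labels.

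The targeted genes came first. The Nras probe, which is designed on the mouse gene, read 11.87 on the log2 intensity scale in the control and 12.03 ± 0.20 (SD, n = 7) in the resistant tumours, a difference of 0.16 (SE 0.26, limma adjusted p = 0.916). Whether this probe reads the viral transgene is not known, so it checks neither the silencing nor the labels. One of the 2 Cdkn2a probes read 8.23 in the control and 8.98 ± 0.78 (SD, n = 7) in the resistant tumours, with all 7 above the control and an adjusted p of 0.843. Resistant tumour 6 had the highest Cdkn2a level at 10.52, against 8.26 to 9.23 in the other 6. The other Cdkn2a probe was detected on 0 of 8 arrays, the control included. The positions of both probes relative to the deleted exons are not given in the sources used here, so neither checks the deletion.

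Of 10461 genes tested with limma, 1 rose and 22 fell in the resistant tumours relative to the control. Rab5if, a small gene named as an interactor of the endosomal GTPase RAB5, rose 6.20-fold (log2 2.63, SE 0.25, adjusted p = 0.00854), above the control in 7 of 7 tumours. Among the genes that fell, Cacna1g, which encodes a T-type calcium channel, was at least 6.19-fold lower on the probe used (adjusted p = 0.00356). Another Cacna1g probe read 5.63 in the control, where the lowest detected signal was 5.26, and its remaining probe was detected on 0 arrays. Ldoc1 was at least 5.27-fold lower (adjusted p = 0.00356). Nudt6 was at least 4.89-fold lower (adjusted p = 0.00633) and the prolactin family gene Prl3d3 at least 4.39-fold lower (adjusted p = 0.00854). Rspo3, a secreted enhancer of Wnt signalling, was at least 3.65-fold lower, and Fbn2, a fibrillin of the extracellular matrix, at least 3.25-fold lower (adjusted p = 0.0226 for both). These 6 genes were detected in the control and in no resistant tumour. The same held for 15 of the 22 genes that fell, and their folds are lower bounds set by the detection limit. For these 15 the spread behind the p is that of undetected values, so the p shows only that the 1 control array lay above background. Ibsp, the bone matrix sialoprotein, read 8.04 in the control and was detected in 1 resistant tumour, at 5.33 (adjusted p = 0.00825). The homeobox gene Rhox5 read 8.23 in the control and was detected in 2, at 5.62 and 5.78 (adjusted p = 0.0439). Cxadr, the coxsackie and adenovirus receptor, read 6.83 in the control and was detected in 1, at 5.23 (adjusted p = 0.0293). The other Cxadr probes were detected on 0 arrays, the control included. The sizes of these 3 differences are not given, since most resistant tumours lay under the detection limit. Tnfsf11, the cytokine RANKL, fell 5.69-fold (log2 -2.51, SE 0.29, adjusted p = 0.0194) while still detected in all 8 tumours. In the resistant tumours it read 5.28 to 5.92, near the lowest detected signals of their arrays, 5.12 to 5.36. Its fold and SE therefore also rest on values near the detection limit. The rule that named these genes required all 7 resistant tumours below the control, or above it for Rab5if. Of all 10461 genes, 1779 had all 7 below the control and 1396 had all 7 above it. With any 1 resistant tumour left out, Rab5if, Cacna1g, Ldoc1, Nudt6, Prl3d3 and Ibsp still passed (highest adjusted p 0.0398). For all of these but Rab5if, each such fit sets the same control array against values that are mostly undetected. Passing again is therefore no separate check for them. Tnfsf11 did not pass without tumour 2 or 3 (adjusted p = 0.0704 and 0.0537), Rspo3 without tumour 2, 4 or 7 (0.0503 to 0.0764), Fbn2 without tumour 2, 3 or 4 (0.0507 to 0.0782), Cxadr without tumour 2, 3, 4, 5 or 7 (0.0711 to 0.0978) and Rhox5 without tumour 2, 3, 4, 6 or 7 (0.0511 to 0.122). Without background correction, Rspo3, Fbn2 and Cxadr did not pass (adjusted p = 0.0673, 0.0826 and 0.0826), nor with the deposited normalized values (0.0722, 0.0894 and 0.0894), and Rhox5 did not pass with no detection filter (0.0563).

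Several genes, named by the same rule, were higher in all 7 resistant tumours without passing the test. The largest difference among the 9 named was in Cx3cr1, the fractalkine receptor of microglia and macrophages, at 5.47 in the control and 9.43 ± 0.73 (SD, n = 7) in the resistant tumours (adjusted p = 0.0877; 0.0209 without tumour 1, and 0.0209 to 0.21 over the alternatives). Dhrs1 differed by 2.13 (SE 0.32, adjusted p = 0.0591), Rnf4 by 2.63 (SE 0.45, adjusted p = 0.0871) and Clta, a clathrin light chain, by 1.52 (SE 0.25, adjusted p = 0.0807). Gatad1 differed by 2.43 (SE 0.39, adjusted p = 0.073) on the probe used, but by 0.65 and -0.12 on its other 2 probes. Commd3, Gpx1, Rps6 and Rdm1 differed by 1.46, 1.63, 1.77 and 1.63, with adjusted p between 0.0807 and 0.164. Leaving out 1 tumour made Dhrs1 (tumour 5), Gatad1 (tumour 1), Clta and Commd3 (tumour 6) and Rnf4 (tumour 7) pass, at adjusted p from 0.0173 to 0.0409. At an unadjusted p under 0.05, 299 genes were higher and 560 lower. The residual spread came from the 7 resistant tumours alone, and the control was assumed to vary like them. The number of genes that fell was 5, 8, 11 and 14 without resistant tumours 2, 3, 4 and 7, and 50 and 36 without tumours 1 and 6. The number that rose was 8 without tumour 1, 3 without tumour 6 and 2 without tumour 5 or 7.

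Of 24 gene lists tested with limma's camera, 2 were higher in the resistant tumours and 0 lower, and no member of any list passed the test over all genes. Both list calls were lost with an estimated correlation (adjusted p = 0.97 for each) and by fry (adjusted p = 0.363 for macrophage and 0.919 for muscle genes). In the list of macrophage and myeloid genes (camera adjusted p = 0.0351), 7 of 17 measured members were above the control in all 7 tumours and 2 below it. Beside Cx3cr1, the complement genes C1qc and C1qa differed by 1.29 (SE 0.29) and 1.24 (SE 0.37). The lysozyme gene Lyz2, named outside the rule, differed by 2.49 (SE 0.84). Adjusted over the list alone, 2 members were higher. Fry's mixed test, which asks whether members differ in either direction, passed for this list and for no other. It too rests on the spread of the resistant tumours alone. The scavenger receptor gene Cd163, also named outside the rule, went the other way on average. It read 8.41 in the control and from 5.87 to 10.30 in the resistant tumours. It is therefore not among the 2 members below the control in all 7. In the list of skeletal muscle genes (camera adjusted p = 0.0351), 0 of 18 members passed the test even when adjusted over the list alone, and 4 were above the control in all 7 tumours. The difference lay in some tumours: the mean over the list was 5.38 above the control in resistant tumour 1, 3.03 in tumour 2, 1.59 in tumour 7 and 1.40 in tumour 6. It was -0.14, -0.18 and 0.05 in tumours 3, 4 and 5. Acta1, the actin of skeletal muscle fibres, read 14.15 in tumour 1 and 12.17 in tumour 2 against 5.99 in the control. Both list calls were also lost without tumour 1, 2 or 7 (adjusted p from 0.0506 to 0.108), without background correction (0.0571) and with the mean of a gene's probes (0.0859), and that of macrophage genes under median scaling (0.0828). Over all alternatives the adjusted p went from 0.0189 to 0.97 for macrophage and from 0.000753 to 0.97 for muscle genes.

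The lists closest to the question showed no difference that passed. For comparison with the counts of members here and above, 1779 of all 10461 genes were below the control in all 7 tumours and 1396 above it. In MAPK output, the genes that ERK signalling induces, 4 of 17 measured members were below the control in all 7 tumours and 2 above it (camera adjusted p = 0.522). The immediate early gene Ier3 differed most, by -1.52 (SE 0.41, adjusted p = 0.334). Dusp6, an ERK phosphatase and common readout of the pathway, was named outside the rule. It read 13.16 in the control and 12.21 ± 0.75 (SD, n = 7) in the resistant tumours, below the control in 6 of 7. The difference was -0.95 (SE 0.70, adjusted p = 0.782). Etv5 was 7.53 in the control and above it in all 7, by 0.75 on average (SE 0.71). In the RAS-MAPK core list, Rasa1 and Nf1, which encode inactivators of RAS, differed by -1.14 (SE 0.46) and -0.76 (SE 0.37), below the control in 7 of 7 (list adjusted p = 0.592). In the PI3K-AKT core list, Pdpk1 differed by -1.31 (SE 0.51) and the list did not pass (adjusted p = 0.866).

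Receptor tyrosine kinases and their ligands did not differ as lists (adjusted p = 0.939 and 0.814), although members differed in single tumours. Of 32 receptors measured, 4 were above the control in all 7 tumours and 6 below it. Mst1r, the receptor for macrophage-stimulating protein, read 6.62 in the control and was detected in 2 resistant tumours, at 5.33 and 5.54 (adjusted p = 0.133). It was the 1 receptor to pass when adjusted over the list alone. Egfr, detected in all 8 tumours, differed by -2.09 (SE 0.81) on the probe used, and by -1.02 and -1.30 on its other detected probes. Epha7 read 6.70 in the control and was detected in 2 resistant tumours, at 5.45 and 6.16. Of 25 ligands, 3 were above the control in all 7 tumours and 5 below it. Nrg1, the neuregulin ligand of ERBB receptors, read 9.34 in the control and 6.76 ± 1.10 (SD, n = 7) in the resistant tumours. Nrg1 was not detected in tumour 6, so that mean and SD include a value under the detection limit. Hbegf differed by -1.38 (SE 0.59) and Pros1 by -1.43 (SE 0.53). Met, the receptor for hepatocyte growth factor, was chosen after its values were seen. It was not detected in the control and was at least 33.5-fold higher in resistant tumour 2, at least 19.0-fold in tumour 4 and at least 23.8-fold in tumour 7. It was at least 1.58-fold higher in tumour 5 and not detected in tumours 1, 3 and 6. Its ligand Hgf, also chosen after its values were seen, was 6.41-fold, 4.02-fold and 7.15-fold above the control in tumours 2, 4 and 7. These folds compare 1 array with 1 array and have no replicate check. Pdgfra read between 12.28 and 12.75 in 6 resistant tumours and 12.57 in the control, but 9.79 in tumour 6.

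**Figure D1:**
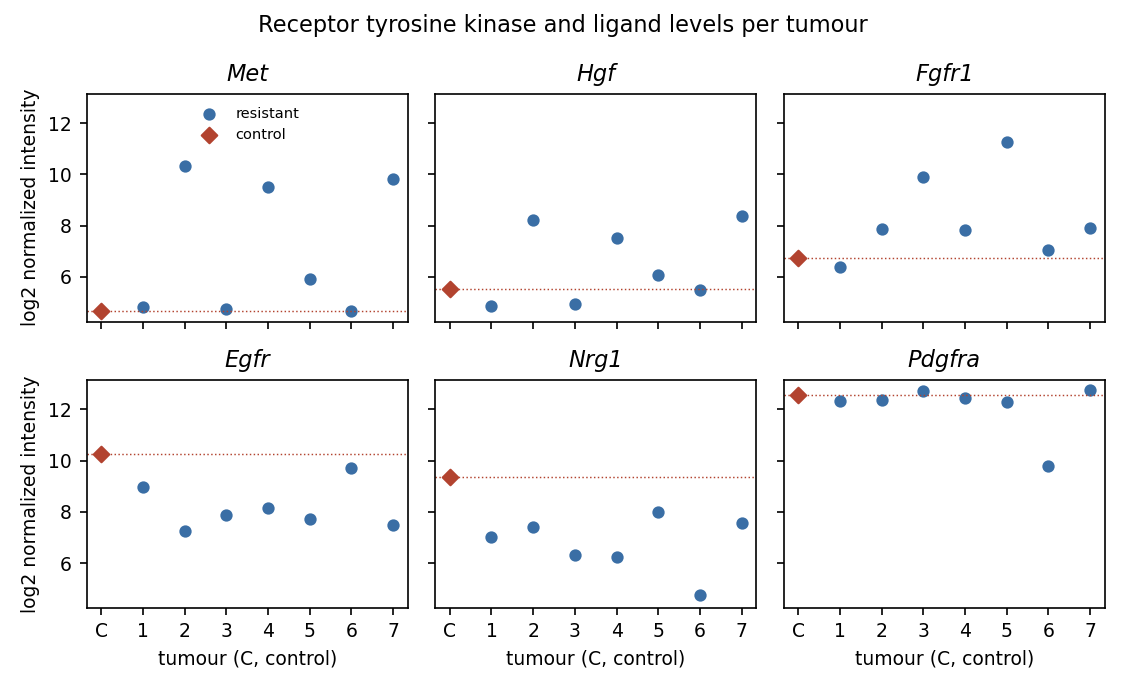
Log2 normalized intensity (vertical axis) of 4 receptor tyrosine kinases and 2 ligands in the control (C, diamond, with its level as a dotted line) and in resistant tumours 1 to 7 (circles), 1 array each. Met read 10.32, 9.51 and 9.83 in tumours 2, 4 and 7 against 4.65 in the control, where it was not detected, and Fgfr1 read 9.91 and 11.25 in tumours 3 and 5 against 6.75.

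Of 21 melanocyte pigmentation genes with a probe, 12 were detected in none of the 8 tumours, among them Mitf, Tyr, Tyrp1, Dct, Mlana and Pax3. The 9 that were measured did not differ as a list (adjusted p = 0.866). The endothelin receptor gene Ednrb, named outside the rule, read 9.60 in the control and between 8.76 and 10.00 in the resistant tumours. Among neural crest and Schwann cell genes (list adjusted p = 0.639), the transcription factor gene Tfap2b read 10.30 in the control and 8.71 in resistant tumour 1, and was not detected in the other 6 (adjusted p = 0.352). It passed without tumour 1, when only undetected resistant values remain, so that p is not given. The adhesion gene Nrcam, detected in 6 of the 7, differed by -3.53 (SE 1.44) and the progenitor marker Nes by -2.30 (SE 1.32). Among fibroblast genes, Thy1 differed by -3.10 (SE 0.77, adjusted p = 0.289) and Fbln2 by -2.88 (SE 1.21), and among mesenchymal transition genes the matrix protein gene Tnc differed by -3.38 (SE 1.58) and Snai1 by -0.80 (SE 0.21). Neither list passed (adjusted p = 0.522 and 0.499). The p53 targets had the smallest adjusted p among the lists tested as lower, 0.0692, with 5 of 15 members below the control in all 7 tumours. Ccng1 differed by -1.06 (SE 0.36) and Pmaip1, which encodes the apoptosis inducer NOXA, by -1.58 (SE 0.56). That list passed without resistant tumour 4 (adjusted p = 0.0474) or 6 (adjusted p = 0.0458), and went up to 0.97 over the alternatives.

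The remaining lists did not pass either. Proliferation genes had an adjusted p of 0.639, with the replication gene Mcm5 at 10.53 in the control and 11.45 ± 0.45 (SD, n = 7) in the resistant tumours. The member with the smallest p, the ubiquitin-conjugating enzyme gene Ube2c, went the other way, at 6.03 in the control and below it in 7 of 7, detected in 4 of them (adjusted p = 0.604). Interferon response genes had 0.866, antigen presentation 0.515, hypoxia and glycolysis 0.437, oxidative phosphorylation 0.639, endothelial 0.814, smooth muscle and pericyte 0.522, lymphocyte 0.866, keratinocyte 0.866, adipocyte 0.814 and housekeeping genes 0.973. Erythrocyte genes had 0.134, and without tumour 5 they passed as lower (adjusted p = 0.00645, with 0.00645 to 0.97 over the alternatives). The mean over the list and the test differed in sign for the pigmentation, interferon, lymphocyte and keratinocyte lists. For the PI3K-AKT core, receptor tyrosine kinase, interferon, oxidative phosphorylation and keratinocyte lists the median differed in sign from the mean.

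**Figure D2:**
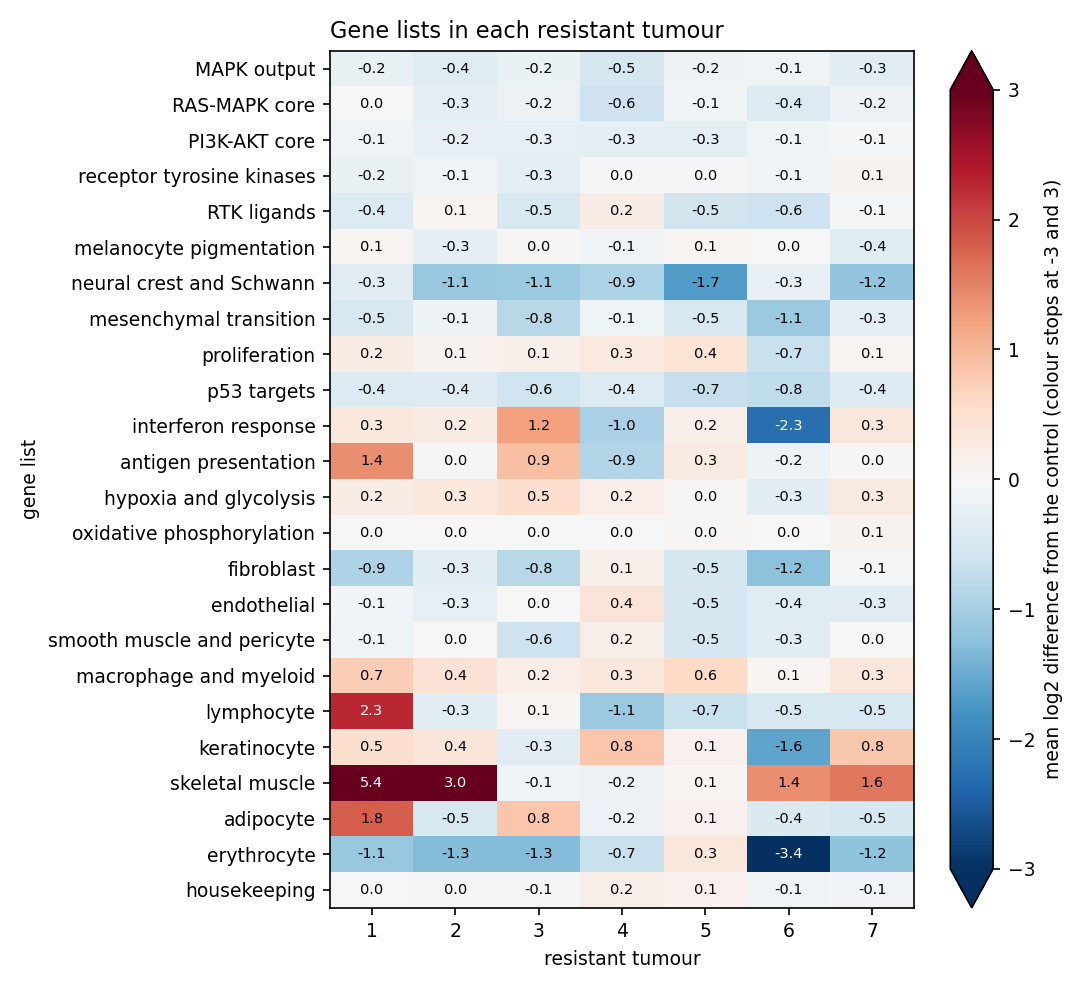
Mean log2 difference from the control over the measured genes of each of 24 lists in each of the 7 resistant tumours, 1 array per tumour. The skeletal muscle list reached 5.38 in tumour 1 and 3.03 in tumour 2, the lymphocyte list 2.26 in tumour 1, and the erythrocyte and interferon response lists -3.44 and -2.25 in tumour 6.

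Set against the control on its own, each resistant tumour had between 525 and 1214 genes at least 2-fold higher and between 552 and 1383 at least 2-fold lower, with medians of 689 and 908. Under median scaling, where the median difference of all genes was -0.20, these medians were 485 and 1348. They were 344 and 447 without background correction and 386 and 509 with the deposited normalized values. Resistant tumour 6 gave the highest count in both directions. Across genes, the control correlated with the resistant tumours at a mean Pearson coefficient of 0.933, and the resistant tumours among themselves at 0.933, from 0.878 to 0.981. The difference of -0.00077 had an exact two-sided permutation p of 1 over the 8 choices of the tumour set apart. The smallest p possible there is 1 in 8, and genes are not independent replicates. Tumour 6 had coefficients of only 0.878 to 0.903 with the other tumours, and without it the difference was -0.0092. With each of the 8 tumours in turn set against the other 7 in limma, resistant tumour 6 differed in 553 genes, 388 higher and 165 lower. Tumour 1 differed in 47, the control in 23, tumours 3, 4 and 5 in 4, 6 and 7, and tumours 2 and 7 in 0, with 69 and 398 genes at an unadjusted p under 0.05. Genes higher in the tumour set apart were 46 of 47 for tumour 1, 4 of 4, 6 of 6 and 7 of 7 for tumours 3, 4 and 5, and 22 of 23 for the control. With 1 of the other resistant tumours left out, tumour 6 gave 380 to 622 genes, tumour 1 gave 26 to 63 and the control 6 to 58. Without tumour 6 the highest count was 51, for tumour 1. The control lay outside the range of the 7 resistant tumours in 30.4% of genes, where chance gives 25%.

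**Figure D3:**
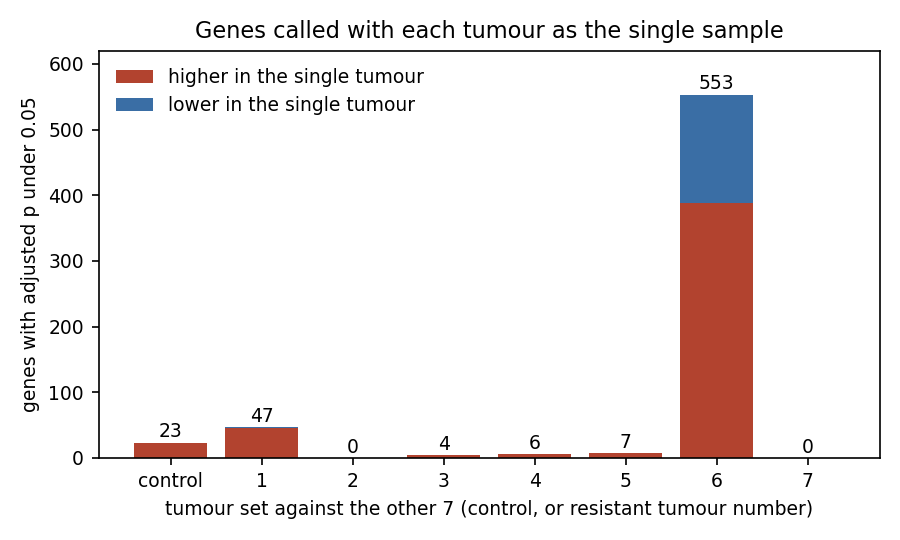
Number of genes with an adjusted p under 0.05 (vertical axis) when each of the 8 tumours is set against the other 7, split into genes higher and lower in that tumour. Tumour 6 reached 553 genes, tumour 1 47 and the control 23.

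The genes that set tumour 6 apart were chosen after their values were seen. The synaptic ligand gene Nxph1 was at least 93.3-fold higher there than in the other 7 tumours, the gastrin receptor gene Cckbr at least 86.9-fold, and Olfm2 and Igfbp2 at least 95.3-fold and 47.8-fold. None of these 4 was detected in another tumour, so their p-values are not given. The keratin gene Krt8 was 164-fold lower in tumour 6 (adjusted p = 0.013), the galectin gene Lgals3 12.3-fold lower, the calcium-binding protein gene S100a4 15.1-fold lower and the chemokine gene Ccl2 18.6-fold lower.

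The 7 resistant tumours varied more in most lists than random genes of like expression did. For 16 of 24 lists, the median SD over the 7 tumours was at or above the 95th percentile of 10000 random lists of the same size, and for 14 to 17 lists with 1 tumour left out. Among the 16, proliferation genes were at the percentile 35.0 without tumour 6 and endothelial genes at 68.9 without tumour 4. Smooth muscle and pericyte genes were at 83.1 without tumour 4, 92.2 without tumour 2 and 93.3 without tumour 5. Proliferation genes were also at 94.5 without background correction and 94.0 with the deposited normalized values. Smooth muscle and pericyte genes were at 92.4 at detection p under 0.01, and macrophage genes at 94.7 with no detection filter. The other crossings were of lists that rose past the limit. The random lists were drawn gene by gene, whereas members of some lists move together. The estimated inter-gene correlation was 0.89 for skeletal muscle, 0.81 for lymphocyte and 0.65 for interferon genes. In such lists 1 tumour can raise the SD of many members at once, so their percentiles are overstated. The estimate was -0.0054 for receptor tyrosine kinases, -0.027 for MAPK output and 0.10 for RTK ligands. For RTK ligands the median SD was 0.97 (percentile 100), for receptor tyrosine kinases 0.58 (99.9) and for MAPK output 0.55 (99.4), while pigmentation genes lay at 0.42 (77.4) and housekeeping genes at 0.19 (5.35). Skeletal muscle genes had the largest median SD, 2.03. The most variable single genes were Gldn, the gene of the node of Ranvier protein gliomedin (SD 4.03), Acta1 (3.82), Krt20 (3.43) and Myl1 (3.26). They were followed by the neuropeptide gene Gal (3.19), the growth factor gene Igf2 (3.17), Htr5b (3.12), Krt8 (3.09), Mdk (3.04) and Tnnc2 (3.04). Of these, Gldn, Krt20 and Htr5b were detected in 3 resistant tumours and Gal in 2, so their SDs include values under the detection limit, as do those of Acta1, Myl1 and Tnnc2, detected in 5, 5 and 4.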

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

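The tests of array quality and of scaling for tumour 6 were chosen after the result was seen, whereas the nerve markers and their bounds were written before their levels were seen. Among 108 named genes and 24 lists, 23 had 1 of the 7 resistant tumours farther from the rest than the gap test for 7 values allows. Tumour 6 accounted for 17 of the 23. Of the 108 genes, 15 were named for their spread or for having 1 tumour apart, so these counts cannot be set against chance. Among the other 93 genes, 13 had 1 tumour apart, 9 of them tumour 6, where chance gives about 1 in 20 and genes are not independent.

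In tumour 6, Cdkn2a read 10.52 on the log2 scale against at most 9.23 in the other 6, Ddr1 9.53 against at most 8.11, Etv5 9.79 against at most 8.52, Fgf1 8.50 against at most 5.18 and Alk 7.02 against at most 5.08. Near the detection limit, Ibsp read 5.33 and Cxadr 5.23 there. Lower in tumour 6 than in the other 6 were Pdgfra at 9.79, Krt8 at 5.18, Ifit2 at 5.44, Emp1 at 12.87, Clta at 12.12, Mcm5 at 10.48, Slc2a1 at 10.19 and Gapdh at 13.91. The mean difference from the control in tumour 6 was -0.67 for proliferation genes and -3.44 for erythrocyte genes. In tumour 1, Tfap2b read 8.71 and Cd79a 5.36, and the lymphocyte list lay 2.26 above the control, against 0.05 or less in the other 6. Slc4a1 read 6.08 in tumour 5, and Gusb read 11.61 in tumour 3, below the other 6. The oxidative phosphorylation list lay 0.12 above the control in tumour 7.

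For tumour 6, a dim array is argued against by its detected probes, 12851, more than on any other array. Its raw median of 91.3 also lay within the range of the arrays, 86.3 to 94.8. Its lowest detected signal, 5.12 on the log2 scale, was the lowest of the 8, which can raise the count of detected probes. That count does not measure RNA degradation, which was not tested. Scaling is argued against because tumour 6 gave at least 9.09 times as many genes as the next tumour without background correction, under median scaling, under cyclic loess and with the deposited normalized values. Admixed peripheral nerve may contribute and cannot be told apart from a tumour that expresses glial genes: the median of 6 measured myelin genes was 0.82 higher in tumour 6 than in the mean of the other 7, between the bounds set for and against nerve, and 4 of the 6 were detected in all 8 tumours. Dhh (11.10), Cnp (10.04) and Drp2 (7.19) were highest there, but Mbp, an abundant myelin transcript, read 6.15 against 6.10 to 7.01 elsewhere. No biological explanation was tested, since the labels give tumour 6 no group of its own.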

How the results depend on the processing

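The alternatives for the counts with each tumour in turn set apart, and leaving out a tumour for the spread of lists, were chosen after seeing the data, and all others were planned. All 23 genes that passed kept their sign under every alternative in which they were tested. Of them, 23 still passed under median scaling, cyclic loess and the trended, robust variance, 22 with no detection filter and with probe means, 21 at detection p under 0.01, 9 without background correction and with the deposited normalized values, and 6 to 23 with 1 resistant tumour left out. Requiring detection on all arrays left 3 of them to test, of which 2 passed. The count of genes higher was 3 under cyclic loess and under the trended variance and 4 with no filter, and leaving out 1 resistant tumour gave 1 to 8. The count lower was 9 without background correction, 8 with the deposited values, 1 with detection on all arrays and 35 with no filter, and leaving out 1 tumour gave 5 to 50. Lists higher numbered 0 without background correction, with probe means, with an estimated correlation and by fry. They numbered 1 under median scaling and with detection on all arrays, and 0 to 2 without 1 tumour. With detection on all arrays the skeletal muscle list was not tested, since only 3 members were detected on all arrays and 5 were needed. Lists lower numbered 0 to 1 without 1 tumour. The median count of genes at least 2-fold higher was 344 without background correction and 386 with the deposited values; lower, it was 447, 509 and, with detection on all arrays, 510. The cause was not tested, except that requiring detection on all arrays tests fewer genes (7314) and background correction by construction widens differences of dim probes. Median scaling moved the median of all genes to -0.20, so differences under it are relative to that. The correlation difference changed sign with 1 tumour left out (-0.0092 to 0.0046), and so few tumours allow no p under the threshold. Variable lists numbered 15 to 17 under the processing alternatives and 14 to 17 without 1 tumour, with single lists crossing the limit 9 and 8 times. The highest count with a tumour set apart was 472 to 618 under 4 processing alternatives and 51 to 622 without 1 tumour, 51 being that without tumour 6. Other filters, probe rules and variance models were not run for it. The variance model does not enter the counts of 2-fold genes, the correlation or the spread. Among named genes 13 alternative values newly passed and 25 no longer did, and among lists 3 and 15; none that passed changed sign. A block for chip was not run because the columns give none. No paired analysis was possible because the sample titles pair no resistant tumour with the control.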

Other observations

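The tests of scaling and background correction and the count over choices of the tumour set apart were chosen after the results were seen, whereas the muscle markers were written before their levels were seen. The genes of this and the next paragraph were chosen after their values were seen. Fgfr1 was 22.7-fold above the control in resistant tumour 5 and 8.96-fold in tumour 3, and 2.13-fold to 2.23-fold in tumours 2, 4 and 7, the tumours with the highest Met and Hgf levels. In tumours 1 and 6 Fgfr1 was at 0.769 and 1.24 times the control and Met was not detected. Tumours 2 and 7 were the most alike pair, with a Pearson coefficient of 0.981 across genes. Interferon response genes were highest in tumour 3, with 14 of 20 at least 2-fold above the control, and lowest in tumour 6, with 15 of 20 at least 2-fold below it: Usp18 read 12.01 in tumour 3, 10.15 in the control and 5.66 in tumour 6. Tumour 4 had 11 of 20 at least 2-fold below the control.

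Compared with the other 7 tumours, in resistant tumour 1 the plasma cell gene Mzb1 was 51.9-fold higher (limma adjusted p = 0.016), Cd8b1 of cytotoxic T cells 13.1-fold higher (adjusted p = 0.0359) and the brown fat gene Cidea at least 12.5-fold higher, detected in no other tumour. Of 19 antigen presentation genes, 14 were at least 2-fold above the control there.

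For the skeletal muscle list, admixed muscle tissue was tested on genes outside the list: tumour 1 was the highest of the 8 in 11 of 11 measured markers, among them Tcap (10.90, against 7.56 in tumour 2 and 5.31 in the control) and Tnnt1 (10.92, against 7.82 and 7.04). This is consistent with muscle fibres in the sample of tumour 1. The list's call does not bear on it, since it was lost without tumour 1 (mean 0.96, adjusted p = 0.108), tumour 2 (1.35, 0.0529) or tumour 7 (1.59, 0.0597), with adjusted p from 0.000753 to 0.97 over the alternatives. Muscle genes expressed by the tumour cells themselves would look the same, which was not tested. Of the 11 markers, 2 were detected in tumour 1 alone, which fixes their outcome, and tumour 1 was the highest in the other 9 of 9; 1 (Nrap) was detected in all 8 tumours.

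For the 23 genes that differ between the control and the resistant tumours, 23 of 23 passed under median scaling and cyclic loess. This argues against scaling between arrays only as applied after background correction, since both start from the same corrected values. For the 15 genes detected in no resistant tumour, passing shows only that the control array stayed above background. Background correction cannot be told apart from the difference itself for the dim genes: without it, 13 of 23 stayed at least 2-fold apart in the same direction. With 8 choices of the tumour set apart, the share that calls as many cannot be under 0.05: the control gave 23 genes, 3 of the 8 choices gave as many, and the highest other was tumour 6 with 553, which points to a structure of the samples other than their groups. The NRAS state of the control, its construct, any difference in doxycycline food and its being 1 tumour are confounded. The biological explanation, NRAS on against off, may be among the causes and stays untested.

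The sex-linked transcripts split the tumours: Kdm5d, a Y-linked gene, was detected in resistant tumours 3 and 5 (6.30 and 6.44) and not in the others, and Xist read 6.94 in the control and 4.73 and 4.79 in tumours 3 and 5. Tumours 3 and 5 also had the highest Fgfr1 levels, so their Fgfr1 difference from the control cannot be told apart from this split. No fit took sex into account.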
